A study of Mus musculus with 11 samples.

How the data were processed

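Messenger RNA was sequenced from colon of C57BL/6 mice, the segment nearest the anus per the labels' protocols, in 11 libraries: 3 of control mice, 4 of mice labelled as AOM/DSS modelled and 4 of mice labelled as creatine supplemented. Azoxymethane (AOM) is a colon carcinogen and dextran sulfate sodium (DSS) in drinking water causes colitis; given together they are a common model of colitis-associated cancer. Per the labels and series text, mice of the model received AOM at 10 mg/kg into the peritoneum, and control mice saline. Mice of the model were then given DSS at 2.5% in 3 cycles, each of 7 days with DSS and 14 days with water. The creatine label names creatine alone, and only the series title places these mice in the AOM/DSS model; the creatine dose and schedule are not given in the sources used here. The labels give no sequencing batch, sex, tumour number or piece position within the segment. Nothing in the labels states that each library came from a separate mouse, so p-values measure the spread between these libraries.

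Per the labels' protocols, RNA was extracted with Trizol, enriched for mRNA and made into circular single-stranded libraries. The submitters' processing notes name the genome build GRCm38.p6; the aligner and the counting tool are not given in the sources used here. One table for the whole series holds 18441 protein-coding genes. The authors deposited an estimated count of reads for each gene and library, not normalized per the file headers. Of these values 89.5% to 91.0% per library were whole numbers, and all were rounded to whole counts before testing. The authors also deposited FPKM values, normalized by them for gene length and depth, and these were used in 1 alternative. The same table holds the authors' log2 fold changes and q-values, made with DESeq2 per the file headers. These are printed only where the authors' deposited table is named. Their direction was checked against log2 ratios of mean CPM over genes above 5 CPM in both groups (correlation across genes 0.9997 to 0.9999). The table holds no immunoglobulin or T-cell-receptor segment gene and no mitochondrially encoded gene. Total counts per library were 14225483 to 17297129. No 2 libraries held identical values.

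Counts were tested with edgeR 4.0.16 in R 4.3.3. Filtering by expression within groups left 14959 genes, and library sizes were scaled by the trimmed mean of M-values (TMM). A robust quasi-likelihood fit over all 11 libraries gave each of 3 comparisons, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. "Adjusted p" below is from this test unless another is named. Standard errors of log2 fold changes were computed from the fold change and its F statistic; a prior count of 2 was used for log2 CPM values in principal components and list means. CPM values are counts scaled to a common depth by edgeR with TMM factors. For a gene without a count in any library of a group, a fold is given as a bound, from a floor of 3 counts in each library; the floor covers counting error only. Fitted folds of genes with a few counts in a group depend on how the model treats low counts, so CPM are given for those.

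35 gene lists (pathways, epithelial cell types, stromal and immune cell types, and markers of neighbouring tissue and handling) were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes; 11 list genes were absent from the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 105 tests of 35 lists in 3 comparisons, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. No camera call held with an estimated correlation in any comparison; the adjusted p of each list with an estimated correlation stands beside it.

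Genes were named by this rule per comparison: the 6 largest increases and 6 largest decreases among genes past the threshold whose groups do not overlap, at a mean of at least 5 CPM, leaving out predicted genes. With fewer than 3 in a direction, it takes the 3 with the smallest p. It adds every creatine list gene, and the 2 genes with the smallest p of each of 7 main lists and of every other list called by camera. A gene named outside this rule is said to have been chosen after its values were seen. Gene positions are from a RefSeq table of the same assembly, GRCm38.p6, matched on the NCBI gene number for 18388 of 18441 genes; start and end count from 1 and cover the whole gene, so exons, introns and UTRs are not told apart.

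The tests were tried on simulated counts for the 14959 genes with 200 genes changed. In AOM/DSS against control the test recovered 6% of genes changed 1.5-fold, 44% at 2-fold, 70% at 4-fold and 90% at 8-fold, with 8.7% of calls false. For creatine against AOM/DSS it recovered 10%, 42%, 80% and 94%, with 3.4% false. For creatine against control it recovered 8%, 44%, 82% and 92%, with 4.2% false. In each comparison a planted list was called and 0 of 34 random lists were. Each gene was drawn independently, so these trials do not cover lists whose genes move together.

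Alternatives, with their effect in the closing section, were DESeq2 1.42.0, size factors by relative log expression or upper quartile, no filter, and a stricter filter (CPM above 1 in at least 4 libraries). Others were a fit of the 2 compared groups alone, the library number as a block, no robust estimation, limma voom with quality weights, limma on log2(FPKM + 1), and leaving out each library. Added after the data were seen were the smooth muscle list mean as a covariate, thinning all libraries to the smallest total, and leaving AOM/DSS library 5 out of the creatine against control fit. The relation between comparisons was compared with 100 simulations without any effect. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The value of 1 gene among the libraries standing apart from their group is not reported here.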

Results

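Expression of 14959 genes was compared between colon of control mice (3 libraries), of mice given azoxymethane and dextran sulfate sodium (AOM/DSS, 4 libraries) and of creatine-supplemented mice of the same series (4 libraries). Total counts were 14225483 to 15984538 in control, 16496024 to 17297129 in AOM/DSS and 16172660 to 16795173 in creatine libraries. Between 16455 and 16815 genes had at least 1 count per library. Libraries are named by group and the number in their label. The first principal component held 69.4% of the variance of log2 CPM. AOM/DSS libraries 2, 6 and 7 lay at 77.3, 122 and 135 on it and AOM/DSS library 5 at -8.52, while creatine libraries lay between -53.9 and -17.9 and controls between -62.0 and -44.2. The root mean square log2 distance of AOM/DSS library 5 to the mean of the other AOM/DSS libraries was 1.09, to the creatine mean 0.503 and to the control mean 0.704.

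**Figure D1:**
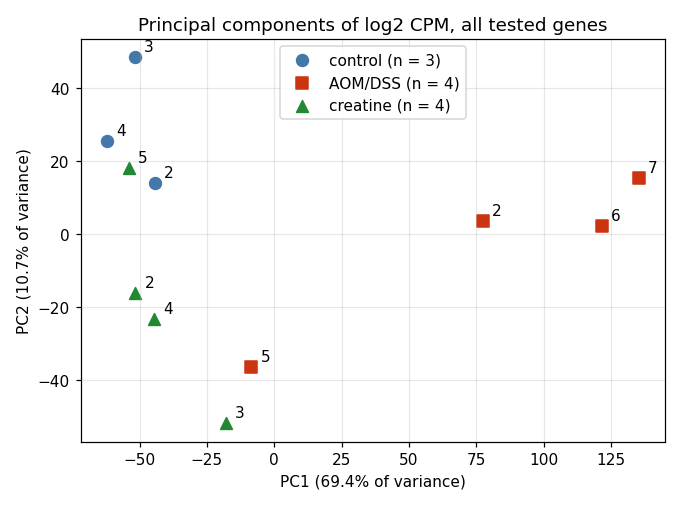
Principal components of log2 CPM over all tested genes, PC1 (69.4% of variance) against PC2 (10.7%), with 1 point per library, numbered as in its label; circles are control (n = 3), squares AOM/DSS (n = 4) and triangles creatine (n = 4). AOM/DSS libraries 2, 6 and 7 lie at PC1 values of 77.3 to 135, and AOM/DSS library 5 lies at -8.52, nearer to the creatine libraries.

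The first comparison asks which genes differ in colon after AOM/DSS. Wnt target and cell division genes rose together. All 23 measured Wnt target genes rose, with a median log2 fold change of 3.32. Among them were Nkd1, a feedback inhibitor of Wnt signalling (365 ± 258 CPM in AOM/DSS, SD, n = 4, against 11.1 ± 3.84 in control, n = 3; log2 fold change 5.04, SE 0.84, adjusted p = 0.00471), and the transcription factor Lef1 (27.6 ± 18.8 against 0.909 ± 0.341 CPM). All 30 proliferation genes rose as well, with a median of 1.82, including the spindle factor Tpx2 (5.28-fold, adjusted p = 0.00399) and topoisomerase Top2a (5.80-fold). Nkd1 and Tpx2 were higher in each of the 4 AOM/DSS libraries than in each control. By camera the adjusted p was 4.2e-11 for Wnt targets and 4.2e-18 for proliferation, and the adjusted p = 0.512 with an estimated correlation for both. Adjusted over the list alone, the counts were again 23 and 30.

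Most cytokine, neutrophil, mast cell and macrophage list genes past the threshold were higher. Of 21 measured cytokine and chemokine genes, 16 rose and none fell (18 rose adjusted over the list alone; median 2.74), and all 12 neutrophil genes rose (12 adjusted over the list alone; median 4.62). The neutrophil chemoattractants Cxcl5 and Cxcl2 stood at 63.0 ± 48.2 and 7.53 ± 4.92 CPM in AOM/DSS and at 0.0439 and 0.0675 CPM in control, and the neutrophil protein gene S100a9 at 9.37 ± 7.05 against 0.0489 CPM. Of 9 mast cell genes, 8 rose (8 adjusted over the list alone; median 4.81); the mast cell protease genes Mcpt2 and Mcpt1 were 35.9-fold (SE 0.44 on the log2 scale, adjusted p = 0.00209) and 28.1-fold higher, and as close relatives may share reads. Of 23 macrophage and dendritic cell genes, 12 rose and 1 fell (14 and 1 adjusted over the list alone); the one that fell was the scavenger receptor Cd163, from 5.53 ± 0.25 to 0.384 ± 0.200 CPM, and Arg1, an arginase of activated macrophages, rose 45.2-fold. Camera gave adjusted p of 8.2e-08, 2.8e-07, 1.2e-07 and 0.00185 for these 4 lists; with an estimated correlation the adjusted p = 0.512 for cytokines and neutrophils, 0.39 for mast cells and 0.621 for macrophages. The T and natural killer cell list was not called (median -0.48; 3 rose, 5 fell; the same counts adjusted over the list alone), nor was the plasma and B cell list (median 1.04; 0 of 15 passed; 0 adjusted over the list alone). The mean log2 CPM of the plasma and B cell list, relative to all 11 libraries, was 2.54 in AOM/DSS library 5. It was -1.51, -1.675 and -2.80 in AOM/DSS libraries 2, 6 and 7 and -1.48 to 0.918 in controls. Only library 5 thus lay above the controls.

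Matrix and Paneth cell genes rose too. Of 14 matrix protease genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 3.22, or 2.93 with a gene absent from control at its bound), among them Mmp14 (4.41-fold). Of 20 fibroblast and collagen genes, 13 rose and 1 fell (15 and 1 adjusted over the list alone; median 1.20), with Col1a1 4.78-fold and Col1a2 2.94-fold higher. Of 10 Paneth cell genes, 8 rose (10 adjusted over the list alone; median 9.10, or 6.71 with 5 genes absent from control at their bounds); lysozyme Lyz1 rose 92.5-fold, from 10.4 ± 4.99 to 961 ± 626 CPM. The alpha-defensin genes Defa24 and Defa17 were at least 791-fold and at least 410-fold higher than in control, where they had no count (at least 520-fold for Defa24 without AOM/DSS library 6); near-identical alpha-defensin copies can share reads, so single members are uncertain. Of 12 squamous epithelium genes, 9 rose (9 adjusted over the list alone). Camera gave adjusted p of 0.000402, 3.2e-05, 3.2e-05 and 0.00168 for the 4 lists, with the adjusted p = 0.512 with an estimated correlation for each. For genes of the endoplasmic reticulum stress response 8 of 18 rose and 2 fell (9 and 2 adjusted over the list alone), Pdia4 among them at 2.21-fold; the camera adjusted p was 0.0468, and the adjusted p = 0.686 with an estimated correlation. That call ended without creatine library 3 (0.0607), AOM/DSS library 2 (0.0677), AOM/DSS library 5 (0.54) or control library 3 (0.123).

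Genes of absorptive epithelium and of oxidative metabolism fell. Of 34 colonocyte genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone; median -1.62). The basolateral bile acid transporter subunit Slc51a went from 146 ± 37.8 to 0.254 ± 0.239 CPM (log2 fold change -9.19, SE 1.81, adjusted p = 0.00642). Clca4b, the list member that rose, went from 19.5 ± 20.8 to 905 ± 628 CPM (log2 fold change 5.54, and 6.91 without control library 4); reads may be shared with its neighbouring relatives. Decreases were also seen for Osr2 (77.8 to 0.131 CPM), Sis (19.1 to 0.0882), Slc30a10 (21.3 to 0.173), Cyp4b1 (184 to 1.61) and Ugt2b5 (45.4 to 0.675). Without AOM/DSS library 5 the log2 fold changes went from -7.73 to -9.57 for Sis, -6.95 to -8.11 for Slc30a10, -6.88 to -7.79 for Cyp4b1 and -6.12 to -8.27 for Ugt2b5. Fatty acid oxidation genes fell in 28 of 33 cases (29 adjusted over the list alone; median -1.14), with Ehhadh, a peroxisomal enzyme, 4.13-fold lower. Oxidative phosphorylation genes fell in 40 of 47 cases (42 adjusted over the list alone; median -0.60). Of 15 enteroendocrine genes, 6 fell (6 adjusted over the list alone), including Nts, the neurotensin gene (31.0 ± 11.7 to 1.60 ± 0.46 CPM). Of 10 tuft cell genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with Sh2d6 3.55-fold lower. Camera adjusted p was 2.8e-08, 1.1e-12, 1.9e-11, 0.000133 and 0.00329 for these 5 lists, and the adjusted p = 0.512 with an estimated correlation for each.

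Tissue markers moved in the same libraries. Of 17 smooth muscle genes, 7 fell (8 adjusted over the list alone; median -1.50; camera adjusted p = 5.5e-05, adjusted p = 0.613 with an estimated correlation). Myh11, smooth muscle myosin, chosen after its values were seen, stood at 257, 547, 99.6 and 35.8 CPM in AOM/DSS libraries 2, 5, 6 and 7 and at 278, 1041 and 1628 CPM in the controls. Of 13 adipocyte genes, 11 fell (11 adjusted over the list alone; camera adjusted p = 2.7e-07, adjusted p = 0.512 with an estimated correlation), with Cidec 10.8-fold lower. Of 19 enteric neuron and glia genes, 5 fell and 1, the receptor Ret, rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.00586, adjusted p = 0.695 with an estimated correlation; 0.155 by camera without control library 4). The adjusted p of Ret itself was 0.013, and 0.0526 without control library 3. The epithelial gene Epcam, also chosen after its values were seen, was at 1880 ± 263 CPM in AOM/DSS and 2021 ± 57.2 in control (adjusted p = 0.587).

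**Figure D2:**
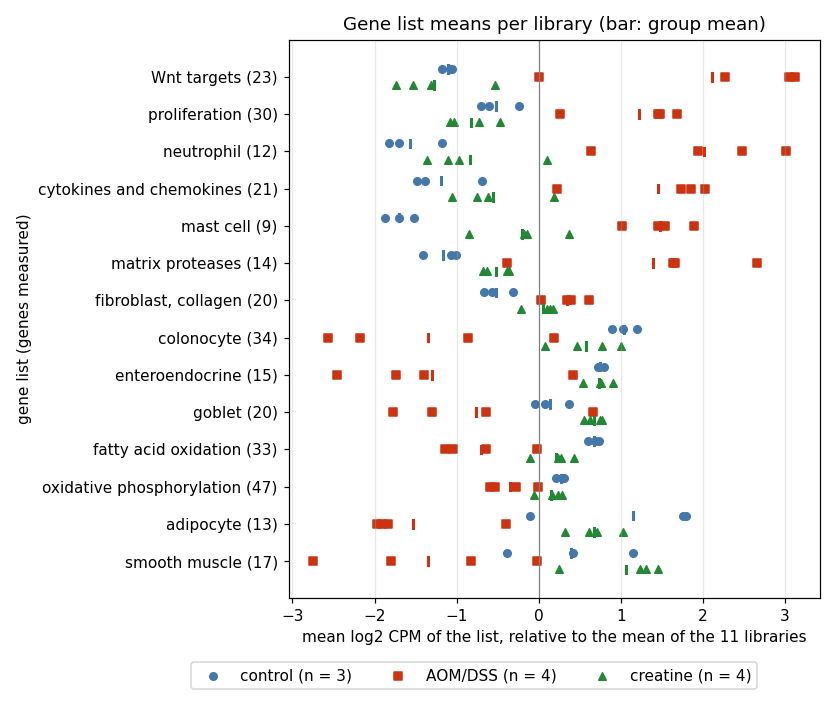
Mean log2 CPM of 14 gene lists per library, relative to the mean of all 11 libraries (x axis), with the number of genes measured in each list in brackets; symbols are libraries of control (n = 3), AOM/DSS (n = 4) and creatine (n = 4), and short bars are group means. The mast cell list lies between 1.02 and 1.89 in AOM/DSS, between -0.845 and 0.363 in creatine and between -1.88 and -1.52 in control libraries.

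In all, 5904 genes passed the threshold between AOM/DSS and control, 3200 higher and 2704 lower, 2832 of them at least 2-fold (absolute log2 fold change of 1 or more). The 2 groups did not overlap for 39.5% of genes, against 5.71% by chance for 4 against 3. The count fell to 3708 without AOM/DSS library 6, 3805 without library 7, 3251 without control library 3 and 3412 without control library 4, and was 8501 without AOM/DSS library 5. It was 3530 in a fit of these 2 groups alone, 9754 with limma voom, and 65 with the smooth muscle mean as a covariate, which moves with the group. With the authors' FPKM the median log2 fold change of all genes was 0.195, against 0.03 in the count fit, with 68.2% of calls higher against 54.2%; the median of each of the 19 called lists kept its sign.

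The second comparison asks how colon of creatine-supplemented mice differed from that of AOM/DSS mice. Wnt target and proliferation genes were lower with creatine: all 23 Wnt targets fell (median log2 fold change -3.97) and all 30 proliferation genes fell (median -2.19), the same counts adjusted over the list alone. The intestinal stem cell receptor Lgr5, on chromosome 10 (115450314 to 115587780), had 82.6 ± 62.4 CPM in AOM/DSS (n = 4) and 1.18 ± 0.88 CPM in creatine libraries (n = 4), a log2 fold change of -6.11 (SE 0.92, adjusted p = 0.00376), with all 4 creatine libraries below all 4 AOM/DSS libraries. Its value in AOM/DSS library 5 was 5.8 CPM, and 70.1 to 156 CPM in the other AOM/DSS libraries. Mki67, a marker of dividing cells, fell from 221 ± 46.3 to 60.7 ± 7.9 CPM (adjusted p = 0.00341). Camera adjusted p was 1.0e-14 and 8.7e-30 for the 2 lists, and the adjusted p = 0.512 with an estimated correlation for both.

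Of 21 cytokine and chemokine genes, 13 fell with creatine (15 adjusted over the list alone; median -2.14), among them Cxcl2 (7.53 ± 4.92 to 0.0955 ± 0.0597 CPM). Neutrophil genes fell in 11 of 12 cases (11 adjusted over the list alone; median -3.60), and mast cell genes in 7 of 9 (7 adjusted over the list alone; median -1.82), with Mcpt2 6.09-fold lower. In the macrophage and dendritic cell list 7 of 23 fell and 1 rose (6 and 1 adjusted over the list alone): Arg1 was 51.8-fold lower, and Cd163 rose from 0.384 ± 0.200 to 1.44 ± 0.10 CPM (adjusted p = 0.0597 with FPKM). Paneth cell genes fell in 9 of 10 cases (10 adjusted over the list alone; median -7.32), with Defa17 at least 449-fold lower and uncertain as a single alpha-defensin copy. The epithelial protease Mmp7 went from 400 ± 275 to 1.31 ± 2.09 CPM (log2 fold change -8.22, and -10.53 without creatine library 3). Matrix protease genes fell in 9 of 14 cases and 1 rose (9 and 1 adjusted over the list alone), and squamous genes in 7 of 12 (7 adjusted over the list alone), Krt13 among them at 13.4-fold. Camera gave adjusted p of 1.3e-05 for cytokines, 2.9e-06 for neutrophils, 0.000523 for mast cells, 0.026 for macrophages, 5.6e-06 for Paneth cells, 0.00951 for matrix proteases and 0.0157 for squamous genes. With an estimated correlation the adjusted p = 0.512 for the first 3 and for Paneth cells, 0.716 for macrophages and 0.613 for the others. The macrophage call ended without creatine library 5 (0.086) or AOM/DSS library 5 (0.0523), and the squamous call without AOM/DSS library 6 (0.0638) or with no filter on low counts (0.0779).

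Differentiated epithelial and metabolic genes were higher with creatine. Of 34 colonocyte genes, 18 rose and 1 fell (28 and 1 adjusted over the list alone; median 1.47); Guca2b, which encodes uroguanylin, rose 1.77-fold and Clca4b fell 48.0-fold. Of 20 goblet cell genes, 3 rose (2 adjusted over the list alone; median 0.94), Bcas1 at 2.89-fold among them. Its adjusted p of 0.0196 was 0.0501 without AOM/DSS library 2 and 0.0587 without library 6, and its log2 fold change of 1.53 was 2.25 without library 5. Of 15 enteroendocrine genes, 6 rose (6 adjusted over the list alone), with Tph1, the enzyme of serotonin synthesis, at 37.6 ± 4.0 against 8.39 ± 6.98 CPM (log2 fold change 2.17, and 2.93 without AOM/DSS library 5). Tuft cell genes rose in 6 of 10 cases and fell in 1 (8 and 1 adjusted over the list alone). Oxidative phosphorylation genes rose in 37 of 47 (41 rose and 1 fell adjusted over the list alone; median 0.47), and fatty acid oxidation genes in 21 of 33 (27 adjusted over the list alone; median 0.87), with Acaa1a 1.89-fold higher. Slc51a rose as well (0.254 to 24.5 CPM; log2 fold change 6.60, and 3.11 without creatine library 5, whose value was 91.3 CPM; adjusted p = 0.0755 with limma voom and 0.0742 with FPKM). Camera adjusted p was 1.1e-07, 0.000221, 3.8e-05, 0.00297, 6.9e-09 and 1.9e-07 for these 6 lists. The adjusted p = 0.613 with an estimated correlation for goblet and oxidative phosphorylation genes and 0.512 for the other 4.

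Tissue markers again moved with the group. All 17 smooth muscle genes rose (17 adjusted over the list alone; median 2.22; camera adjusted p = 9.9e-09, adjusted p = 0.512 with an estimated correlation), Smtn at 3.60-fold among them, and Myh11, chosen after its values were seen, was at 634 to 1745 CPM in the creatine libraries. Adipocyte genes rose in 10 of 13 cases (12 adjusted over the list alone; camera adjusted p = 8.8e-06, adjusted p = 0.512 with an estimated correlation). Enteric neuron and glia genes rose in 6 of 19 and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.000345, adjusted p = 0.617 with an estimated correlation). Of the lists not called, immediate early and heat shock genes had 6 of 16 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.166). Tight junction genes had 6 of 20 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0634, 0.0427 without creatine library 3 and 0.0452 without AOM/DSS library 2). Among these Cgn rose 1.61-fold and the pore-forming claudin Cldn2 fell 3.47-fold. Fibroblast and collagen genes had 10 of 20 lower and 1 higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.0896, 0.0498 without AOM/DSS library 5). Plasma and B cell genes had a median of 0.90 (0 of 15 passed; 0 adjusted over the list alone; camera adjusted p = 0.0632). That list was called with upper-quartile factors (0.0387), with no filter (0.0283), and without creatine library 4 (0.0352) or 5 (0.0172), AOM/DSS library 5 (0.00303) or control library 3 (0.0381). Endothelial genes (median 0.34, camera adjusted p = 0.346) were called without creatine library 5 (0.0463). The camera direction, the median and the mean differed in sign here for interferon, endothelial, p53 target, hypoxia and antioxidant genes.

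Genes of creatine handling were measured as a list of 7. Slc6a8, the creatine transporter on chromosome X (73673133 to 73682502), rose from 245 ± 105 CPM in AOM/DSS to 554 ± 49.0 CPM with creatine (log2 fold change 1.18, SE 0.28, adjusted p = 0.0114), higher in each of the 4 creatine libraries than in each AOM/DSS library. Control had 408 ± 113 CPM (adjusted p = 0.0666 for AOM/DSS against control, 0.641 for creatine against control). The call of Slc6a8 between creatine and AOM/DSS held with each library left out. Between AOM/DSS and control, Slc6a8 was lower without AOM/DSS library 5 (log2 fold change -1.07, adjusted p = 0.00218), as were Ckmt1 (0.00298) and Ckmt2 (0.00139). With limma voom Slc6a8 (0.000574), Ckb (0.0106), Ckmt1 (0.000515) and Ckmt2 (0.00154) were lower as well, and with DESeq2 Slc6a8 (0.0426). Creatine kinase genes Ckb (2.56-fold, adjusted p = 0.0269), Ckm (8.62-fold, 0.0323) and mitochondrial Ckmt1 (2.13-fold, 0.044) rose too, while Ckmt2 (adjusted p = 0.0961) and the synthesis enzymes Gatm (0.989) and Gamt (0.769) did not pass. The list's camera adjusted p was 0.028, and the adjusted p = 0.512 with an estimated correlation; adjusted over the list alone 4 genes passed too. Only 1 of the 4 genes passed without creatine library 2, 4 or 5 or AOM/DSS library 6 or 7, 2 passed without AOM/DSS library 2, and 0 with the smooth muscle mean as a covariate. Without any one of creatine libraries 2, 4 and 5 and AOM/DSS libraries 6 and 7 the adjusted p was 0.0543 to 0.0757 for Ckb. Without any one of these or AOM/DSS library 2 it was 0.0592 to 0.0831 for Ckm and 0.0535 to 0.123 for Ckmt1, whose call also ended without creatine library 3 (0.0799), with upper-quartile factors (0.0534), with no filter (0.0533) and with these 2 groups alone (0.0816). The log2 fold change of Ckm was 3.11, and 4.24 without AOM/DSS library 5, and turned to -0.83 (adjusted p = 0.783) with the smooth muscle covariate. Ckmt2 passed without AOM/DSS library 5 (2.61, adjusted p = 0.000866) and with limma voom (0.000705). Ckm, the muscle isoform, was the single list gene past the threshold between AOM/DSS and control (14.8-fold lower, adjusted p = 0.0172, and 0.0936 without control library 4, whose value was 60.8 CPM). Its log2 fold change of -3.89 was -2.49 without that library and -5.02 without AOM/DSS library 5.

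**Figure D3:**
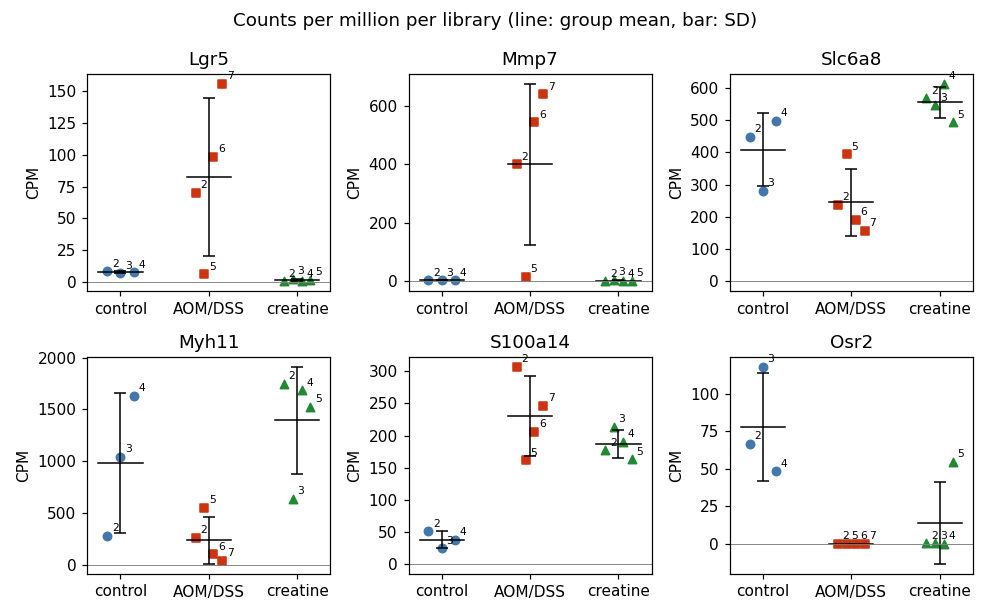
CPM per library for 6 genes (y axis, linear) in control (circles, n = 3), AOM/DSS (squares, n = 4) and creatine (triangles, n = 4) libraries, numbered as in their labels; lines are group means and bars are SD. Slc6a8 lies at 493 to 611 CPM in creatine libraries and 157 to 394 CPM in AOM/DSS libraries, and Osr2 lies at 54.9 CPM in creatine library 5 and below 0.4 CPM in the other creatine libraries and the AOM/DSS libraries.

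Between creatine and AOM/DSS 5920 genes passed the threshold, 2680 higher and 3240 lower, 2510 of them at least 2-fold (absolute log2 fold change of 1 or more), and the 2 groups did not overlap for 28.3% of genes against 2.86% by chance. The count was 3316 without creatine library 2, 3898 without creatine library 5, 3066 without AOM/DSS library 6, 3187 without library 7, and 8827 without AOM/DSS library 5. It was 10410 with limma voom and 0 (919 at an unadjusted p under 0.05) in edgeR with the smooth muscle mean as a covariate. With the authors' FPKM the median of all genes was -0.20, against 0.02 in the count fit, with 27.7% of calls higher against 45.3%. The median of each of the 19 called lists kept its sign. The TMM factors of the count fit were 1.02 to 1.16 in AOM/DSS, 0.90 to 1.00 in creatine and 0.929 to 0.987 in control libraries, so the scaling moved with the group. Whether it caused the shift was not tested.

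**Figure D4:**
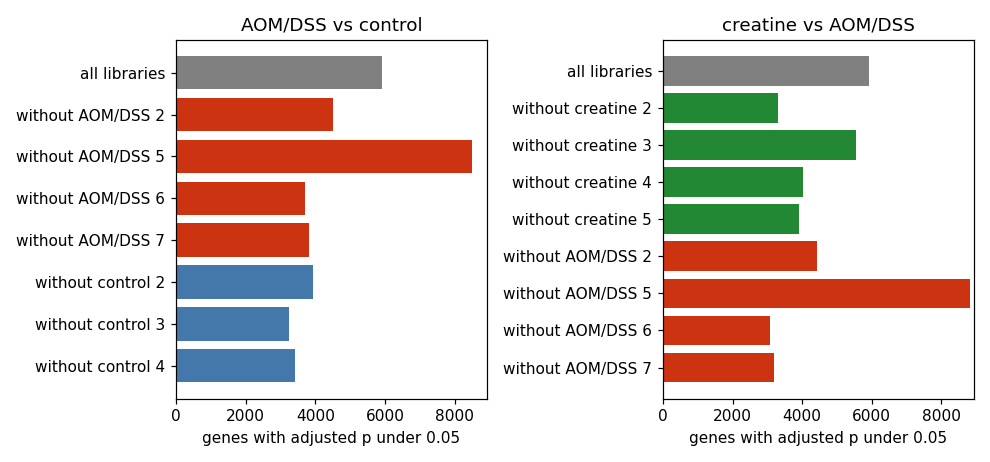
Genes with an adjusted p under 0.05 (x axis) in edgeR with all libraries and with each library of the 2 compared groups left out (y axis), for AOM/DSS against control and creatine against AOM/DSS. Counts run from 3251 to 8501 and from 3066 to 8827, the highest in each panel without AOM/DSS library 5.

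The third comparison sets creatine-supplemented mice against control. Past the threshold were 5 genes, all higher with creatine. They were the calcium-binding protein genes S100a14 (186 ± 21.7 against 37.6 ± 13.2 CPM; log2 fold change 2.31, SE 0.28, adjusted p = 0.0348) and S100a16 (2.58-fold), which lie next to each other on chromosome 3 (from 90526849 and from 90537254), the phospholipase gene Plcd3 (3.48-fold), Fads3 (2.28-fold, adjusted p = 0.0497) and Id1, an inhibitor of DNA-binding transcription factors (1.82-fold). All 5 had also risen in AOM/DSS against control, with log2 fold changes of 2.61, 1.36, 1.84, 1.25 and 0.56. Both comparisons share the control libraries, so low values in these alone favour such agreement. Between creatine and AOM/DSS, the adjusted p was 0.31 for S100a14, 0.971 for S100a16, 0.875 for Plcd3 and 0.766 for Fads3, and Id1 was higher with creatine (log2 fold change 0.31, adjusted p = 0.0336). The call of Fads3 ended with relative log expression factors (0.0513), with no filter (0.0538) and without robust estimation (0.0502). None fell past the threshold; the smallest p among lower genes were those of Vav2 (36.2 ± 5.9 CPM in control, 15.1 ± 2.1 with creatine, adjusted p = 0.0542), Cndp2 (0.0568) and Prss23 (0.0568). All 3 passed with DESeq2 (at most 2.74e-06), limma voom (at most 0.00272), these 2 groups alone (at most 0.0349) and without creatine library 5 (at most 0.0304), and Vav2 with upper-quartile factors (0.0439).

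By camera 20 lists differed from control, though 0 of their genes passed over all genes tested. The mast cell list was higher (median 2.56, camera adjusted p = 2.3e-09; 5 of 9 higher adjusted over the list alone, 0 over all genes), with Mcpt2 at 3.08 ± 1.46 against 0.516 ± 0.084 CPM (adjusted p = 0.0568, 2.95e-05 with DESeq2 and 0.0401 with these 2 groups alone). The fibroblast and collagen list had a median of 0.52 (camera adjusted p = 1.8e-08; 0 adjusted over the list alone). Immediate early and heat shock genes, which respond to tissue handling, had a median of 0.45 (6.9e-07; 2 higher adjusted over the list alone), with Fos at 302 ± 112 against 99.4 ± 33.8 CPM (adjusted p = 0.217, 0.0109 with DESeq2 and 0.0399 with limma voom). These 3 lists were the calls that fry shared (adjusted p of 0.0129, 0.0269 and 0.0274); with an estimated correlation the adjusted p = 0.301 for mast cells and 0.512 for the other 2. Also higher by camera were cytokines (median 0.81, adjusted p = 0.000133; 1 gene adjusted over the list alone), matrix proteases (0.00222), goblet (0.00261), smooth muscle (0.00278), plasma and B cells (median 1.75, 0.00348), squamous (0.00492), neutrophil (0.00653), endothelial (0.00675), endoplasmic reticulum stress (0.00168), macrophage (0.0366; 1 lower adjusted over the list alone) and antimicrobial genes (0.0395; 2 higher adjusted over the list alone). Lower by camera were fatty acid oxidation (median -0.37, 8.2e-07), proliferation (median -0.32, 0.000529), oxidative phosphorylation (0.00701), antioxidant and ferroptosis (0.00975; 1 higher and 3 lower adjusted over the list alone), adipocyte (0.0101) and skeletal muscle genes (0.0114; 2 lower adjusted over the list alone). Adjusted over the list alone the other lists called here had 0 genes. The cytokine median of 0.81 was 0.70 with a gene absent from a group at its bound. Wnt targets had a median of -0.05 (camera adjusted p = 0.412) and colonocyte genes -0.04 (0.142, 0.0241 without creatine library 5 and 0.0298 without control library 3). The camera direction, the median and the mean differed in sign for Wnt target, enteroendocrine, and T and natural killer cell genes. The adjusted p with an estimated correlation was 0.512 for cytokines, matrix proteases, squamous, endoplasmic reticulum stress and antioxidant genes, 0.573 for fatty acid oxidation, 0.613 for antimicrobial and skeletal muscle, and 0.617 for endothelial genes. It was 0.63 for neutrophil, 0.636 for adipocyte, 0.686 for goblet, 0.695 for smooth muscle and plasma and B cells, 0.699 for proliferation, 0.761 for macrophage and 0.826 for oxidative phosphorylation genes.

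Single libraries carried several of these list calls. Without creatine library 3 camera no longer called antioxidant (0.0695), plasma and B cell (0.101), endothelial (0.127), macrophage (0.69), neutrophil (0.147), oxidative phosphorylation (0.406) and squamous genes (0.051). Without control library 3 it lost adipocyte (0.133), antimicrobial (0.369), plasma and B cell (0.0502) and macrophage genes (0.0974); without control library 4 adipocyte (0.186), macrophage (0.371), neutrophil (0.0762) and skeletal muscle genes, whose direction turned (0.478); without control library 2 smooth muscle genes (0.236). Antimicrobial genes were also lost without creatine library 2 (0.0613), creatine library 5 (0.408) or AOM/DSS library 5 (0.0523) and with no filter (0.245), and macrophage genes without AOM/DSS library 5 (0.097). Calls were gained for enteric neuron and glia genes without creatine library 3 (0.0219) or control library 4 (0.000297), interferon genes without creatine library 4 (0.014) or control library 2 (0.0288), posterior homeobox genes without creatine library 5 (0.0164) and hypoxia genes without control library 3 (0.045). Skeletal muscle markers such as Mylpf stood at 22.6 CPM in control library 4 and at 0.861 to 1.98 CPM in the other libraries.

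The count of 5 genes by edgeR stood beside 1620 genes at an unadjusted p under 0.05; DESeq2 gave 334, limma voom 1144 and a fit of these 2 groups alone 194. The 2 groups did not overlap for 18.2% of genes, against 5.71% by chance. The count was 42 without creatine library 5, and 0 without creatine library 2, 3 or 4 or control library 2, 3 or 4 (edgeR; 811 to 1518 genes at an unadjusted p under 0.05). Leaving an AOM/DSS library out of the shared fit gave 15 without library 2, 101 without library 5, and 0 without library 6 (1577 at an unadjusted p under 0.05) or 7 (1662). The count was 77 with the smooth muscle covariate, 21 with libraries thinned to one total and 26 with the authors' FPKM.

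Other lists without a camera call between AOM/DSS and control had these medians: creatine handling -0.74 (called without control library 3, 0.0431), antimicrobial 0.24 (5 of 21 genes rose; 5 adjusted over the list alone; -0.20 with FPKM), interferon 0.26 (4 rose, 4 fell; 3 and 4 adjusted over the list alone), goblet -0.61 (1 of 20 rose; 0 adjusted over the list alone; called without AOM/DSS library 2, 0.0463, or 5, 0.000514, or control library 3, 0.0298, with upper-quartile factors, 0.0386, and with no filter, 0.0283), and tight junction -0.17 (1 rose, 5 fell, among them Ocln at 1.93-fold; 0 and 5 adjusted over the list alone; 0.02 with FPKM). Skeletal muscle genes were high in control library 4 alone (list mean 3.18, with -0.917 and -0.8 in control libraries 2 and 3). Every AOM/DSS library (-0.611 to 0.519) lay above control libraries 2 and 3, so the lower median of that list rests on control library 4. The medians were 0.01 for endothelial, skeletal muscle -1.64 (2 of 6 fell, and called with no filter, 0.026), red blood cell 0.59 (0 of 6 passed) and handling genes 0.04. They were for glycolysis -0.30 (6 rose, 6 fell; 8 and 7 adjusted over the list alone), p53 targets 0.12, hypoxia -0.07 (5 rose, 7 fell; 6 and 7 adjusted over the list alone; 0.08 with FPKM) and antioxidant -0.32 (7 rose, 9 fell; 7 and 10 adjusted over the list alone). The camera direction, the median and the mean differed in sign there for interferon, plasma and B cell, blood, glycolysis, hypoxia and antioxidant genes. In the list of posterior homeobox genes, which mark position along the gut, 2 of 14 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.15, and 0.00933 without creatine library 5). Hoxb6 fell from 36.3 ± 15.8 to 0.64 ± 0.40 CPM, and was chosen after its values were seen.

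The log2 fold changes of AOM/DSS over control and creatine over AOM/DSS were correlated across genes at r = -0.908 (covariance -1.07), and genes are not independent replicates. Both use the AOM/DSS libraries, which alone pushes the correlation below 0: 100 simulations with no effect gave r = -0.456 (SD 0.014) and a covariance of -0.07. The simulations drew each gene independently, so the SD of 0.014 leaves out the spread from genes that move together. It is no measure of how far the observed r lies from no effect. With the AOM/DSS libraries split 2 and 2 so that no library was shared, the mean over 6 splits was r = -0.822 (-0.89 to -0.718) and the covariance -0.96. Without AOM/DSS library 5 the covariances were -1.63 and, split, -1.57. Of 3200 genes higher in AOM/DSS, 2454 were lower with creatine, where independent lists of those sizes would share 693; 1833 of the 2704 lower genes were higher with creatine (484 for independent lists). 2 genes rose in both comparisons and 0 fell in both. The shared AOM/DSS libraries by themselves favour opposite calls, so 693 and 484 are not what no effect would give. These overlaps were not recomputed with the libraries split. Wnt targets, proliferation and neutrophil genes were among those moving in opposite directions, and mast cell genes fell by 1.82 with creatine after a rise of 4.81. AOM/DSS over control and creatine over control, which share the controls, had r = 0.427 (covariance 0.23) against 0.577 (0.094) in simulations with no effect; the covariance was 0.151 without creatine library 3.

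In the authors' deposited table, a q-value under 0.05 was given to 5537 genes for AOM/DSS against control (3062 higher), 6099 for creatine against AOM/DSS (2750 higher) and 951 for creatine against control (506 higher). The authors' deposited table gives Lgr5 log2 fold changes of 3.44 (q = 0.000186) in the first and -6.13 (q = 2.4e-11) in the second, and Slc6a8 -0.75 (q = 0.116) and 1.17 (q = 0.000623). For creatine against control the authors' deposited table gives S100a14 2.31 (q = 8.1e-21) and Lgr5 -2.66 (q = 5.4e-05), and edgeR's adjusted p for that Lgr5 difference was 0.324, against 0.0405 by DESeq2 1.42.0 on the rounded counts and 0.0429 by edgeR without AOM/DSS library 5.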

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

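The tests of explanations in this part, with the counts of splits, thinning and the covariate, were chosen or written down after the results they bear on were seen.

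AOM/DSS library 5 stood apart from the other 3 AOM/DSS libraries, by a gap that took most of the group's range (past Dixon's 95% critical value), in the mean of 4 lists: proliferation (0.257, others 1.45 to 1.69), cytokines (0.222, others 1.73 to 2.02), adipocyte (-0.399, others -1.97 to -1.84) and skeletal muscle (-0.611, others 0.427 to 0.519). For named genes the gap was taken on log2 CPM with a prior count of 2, while the values printed here are CPM. AOM/DSS library 5 stood apart in 8 named genes: Tpx2 (27.9 CPM, others 62.2 to 72.3), Ocln (179, others 117 to 121), Lyz1 (75.7, others 971 to 1450), Arg1 (2.86, others 50.8 to 66.0), Mmp7 (15.6, others 400 to 640), Habp2 (0.655, others 19.5 to 36.4), Mcm6 (47.5, others 92.5 to 104) and Cd22 (35.4, others 1.36 to 2.30). AOM/DSS library 2 stood apart in Nox1 (37.3, others 24.1 to 25.2). Among creatine libraries, library 3 stood apart in Nkd1 (19.0, others 15.1 to 15.4), Ndufv2 (124, others 151 to 157), Cyp2e1 (32.3, others 9.01 to 9.27) and Smtn (93.5, others 192 to 211), and library 5 in Osr2 (54.9, others 0.194 to 0.37), Sis (3.84, others 0.199 to 0.258) and the fibroblast list (-0.217, others 0.105 to 0.169). Chance gives such a gap in about 1 in 20 groups. It was seen in 21 of 304 (6.9%), with genes tested only at a group mean of at least 1 CPM, a limit set after the values were seen. Total count, genes with a count, the share of the top 50 genes, TMM factor, PC1 and PC2 had no such gap in either group.

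The difference between AOM/DSS and control was weighed first. Of the 35 splits of these 7 libraries, 2, the real one included, gave at least 5904 genes, so chance cannot be excluded by this count. The highest other, 8379, places AOM/DSS library 5 with the controls. Less muscle wall in the pieces would raise all epithelial lists alike, but the colonocyte median was -1.62 while Wnt targets were at 3.32, which argues against it as the whole cause. With the smooth muscle covariate the median absolute log2 fold change of the 5904 genes went from 0.95 to 0.55 and the median SE from 0.236 to 0.247, and the Wnt target median from 3.32 to 1.27, so calls ended by smaller folds that the covariate, itself different between groups, had taken up. Library size is argued against by 5779 genes after thinning every library to 14225483 counts. Position within the segment cannot be told apart from AOM/DSS exposure for the falls of Hoxb6 (log2 fold change -5.83), Osr2 and Slc51a. All 3 were low in each AOM/DSS library and the labels give no position. The same limit covers the falls of Sis, Slc30a10, Cyp4b1 and Ugt2b5. These too were low in each AOM/DSS library, and among creatine libraries were highest in library 5 (3.84, 7.75, 75.1 and 22.3 CPM). Hoxd13 rose (log2 fold change 5.59, adjusted p = 0.0348) but was high only in AOM/DSS libraries 6 and 7, and Hoxb13 did not pass (1.84, adjusted p = 0.141). The biological difference, AOM/DSS exposure, stays open beside these explanations and may account for the pattern as a hypothesis.

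The difference between creatine and AOM/DSS was weighed next. Of 35 splits of 8 libraries only the real one reached 5920 genes (highest other 4152). That argues against a random division into 4 and 4. Chance is not excluded, because 1 of 35 is the smallest share this count can give. No split into 4 and 4 sets AOM/DSS libraries 2, 6 and 7 alone against the rest. More muscle wall in the creatine pieces would lower all epithelial lists alike, but the colonocyte median was 1.47 while Wnt targets were at -3.97, which argues against it as the whole cause; with the smooth muscle covariate the median absolute log2 fold change of the 5920 genes went from 0.86 to 0.285, the median SE from 0.214 to 0.274 and the Wnt target median to -1.51, so calls ended by smaller folds and wider errors. A wrong label on AOM/DSS library 5 could not be told apart from a true AOM/DSS sample: its distance of 0.503 to the creatine mean is below the 1.09 to its own group, while its mast cell list mean (1.02, at most 0.363 in creatine and control) and Clca4b (319 CPM, at most 43.6) lie toward its own group, and over 7423 genes on which the other AOM/DSS libraries lie outside the 7 creatine and control libraries it lay outside them the same way for 38.5%, against 37.2% for creatine library 3 and 8.3% to 21.0% for the other 6, each held against the rest of the 7. Creatine library 3 and AOM/DSS library 5 were each other's nearest library (correlation of log2 CPM 0.983). Among creatine libraries, library 3 also lay farthest from the mean of the others (0.624). Its 37.2% is thus not typical of a creatine library, and its own label was not weighed. The share of tumour tissue in the pieces cannot be told apart from an effect of creatine on tumours, since no tumour count is in the labels. AOM/DSS library 5 at -8.52 on PC1, with its group's others at 77.3 to 135, would be one with little such tissue. Creatine supplementation itself stays open, untested against these.

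The difference between creatine and control was weighed last. Of 35 splits, 2, the real one included, gave at least 5 genes (highest other 8, with creatine library 5 placed among the controls). Chance therefore cannot be excluded for a count this small. Osr2 at 54.9 CPM in creatine library 5, below 0.4 CPM in the other creatine libraries and 48.4 to 118 CPM in controls, may reflect a position within the colon segment, or AOM/DSS exposure that took effect in some mice; these cannot be told apart because the labels give the segment and no position in it. Creatine and AOM/DSS exposure are both named by the design for these mice, and neither was tested apart from the other.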

How the results depend on the processing

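The smooth muscle covariate, the thinning and the shared fit without AOM/DSS library 5 were chosen after the data were seen; the other alternatives were planned. For AOM/DSS against control (5904 genes) the count was 3530 with the 2 groups alone, 9754 with limma voom, 65 with the covariate and 3251 to 8501 with single libraries left out (lowest without control 3, highest without AOM/DSS 5). For creatine against AOM/DSS (5920) it was 10410 with limma voom, 0 with the covariate (919 at an unadjusted p under 0.05) and 3066 to 8827 with libraries left out (lowest without AOM/DSS 6, highest without AOM/DSS 5). For creatine against control (5) it was 334 with DESeq2, 8 with upper-quartile factors, 194 with the 2 groups alone, 1144 with limma voom, 26 with FPKM, 77 with the covariate, 21 with thinning, 101 without AOM/DSS library 5 in the fit, and 0 to 42 with libraries left out. With the other normalizations and filters these counts stayed within 1.5 times in each comparison, while single calls ended, those of Ckmt1 and Fads3 among them. Camera made 58 list calls at the preset correlation and 0 with an estimated one. Fry made 38, which shared 15, 16 and 3 with camera in the 3 comparisons. In AOM/DSS against control fry did not call smooth muscle (fry adjusted p = 0.0598), enteric neuron and glia (0.144), macrophage (0.052) and endoplasmic reticulum stress genes (0.0505). In creatine against AOM/DSS it did not call matrix protease (fry adjusted p = 0.0895), enteric neuron and glia (0.0523) and macrophage genes (0.14). The number of creatine list genes called, 4, was 0 with the covariate and 1 to 5 with libraries left out. The relation (r = -0.908) was -0.822 with AOM/DSS libraries split, -0.946 over genes past the threshold in AOM/DSS against control, and -0.937 to -0.876 with libraries left out. Skeletal muscle genes turned direction in creatine against control without control library 4 (adjusted p = 0.478), whose own list mean was 3.18; without other libraries the adjusted p went down to 9.44e-08 (without control library 3). Apart from the covariate, weighed in the part above, the causes of these changes were not tested.

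No sign of pairing by library number was seen. The 6 same-number pairs had correlations of deviations from -0.285 to 0.085 (median -0.0555), and the 34 other pairs from -0.396 to 0.478 (median -0.026). So few pairs cannot exclude a shared batch, which the labels do not give. Numbers 6 and 7 occur only in the AOM/DSS group, so a block by number takes up AOM/DSS libraries 6 and 7 entirely. The comparisons with AOM/DSS then rest on AOM/DSS libraries 2 and 5, and calls lost with the block say nothing about pairing or batch. With the number as a block the counts were 831, 0 (edgeR; 3739 at an unadjusted p under 0.05) and 2, with 0 creatine list calls and 63 list calls. Of 54 named genes called in AOM/DSS against control, 50 had a value in each alternative, and 44 of these kept their call with DESeq2, the other normalizations and filters, the 2 groups alone, no robust estimation, limma voom and each library left out (33 with the block too); 4 others kept it wherever they had a value. Of 56 in creatine against AOM/DSS 48 had a value in each, 39 of these kept their call (0 with the block too) and 6 others kept it wherever they had a value, and of 5 in creatine against control 0 kept it; no called gene turned direction in these. With the covariate 10, 0 and 5 of the 54, 56 and 5 kept their call, and Ckm turned direction in creatine against AOM/DSS; with thinning 53, 56 and 5 kept theirs, and with FPKM 54, 50 and 5 (3 of the 56 were below the FPKM filter). Removing immunoglobulin and T-cell-receptor segments was not run because the table has none, and the pseudocount of 0.1 was not run because counts were deposited. Depth, 14225483 to 17297129 counts, limits genes near the floor of 3 counts per library.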

Other observations

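The genes of this part were chosen after their values were seen, and their values per library are given without a test. Hoxb6 and Hoxb8, of a gene cluster that marks position along the body axis, split the libraries in a way the 3 groups did not. Hoxb9 of the same cluster did not, with 59.2 to 91.9 CPM in controls, 44.2 to 70.3 CPM in creatine and 37.5 to 60.7 CPM in AOM/DSS libraries. Hoxb6 was at 31.5, 53.9 and 23.6 CPM in control libraries 2, 3 and 4, at 13.6 CPM in creatine library 5, at 1.2 to 2.1 CPM in creatine libraries 2, 3 and 4 and at 0.3 to 1.2 CPM in the AOM/DSS libraries. Hoxb8 had 12.2 to 35.9 CPM in controls, 9.4 CPM in creatine library 5 and 0.4 to 1.2 CPM in the other 7 libraries. Slc51a followed the same libraries, with 106 to 182 CPM in controls, 91.3 CPM in creatine library 5 and at most 4.3 CPM elsewhere. Hoxb13 ran from 4.7 CPM in control library 3 to 261 CPM in creatine library 3, and stood at 38.1 CPM in creatine library 5. Hoxd13 was at 59.5 and 132 CPM in AOM/DSS libraries 6 and 7 and at most 6.5 CPM in the other libraries.

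The B cell surface lectin gene Cd22 was at 46.7 CPM in creatine library 3 and 35.4 CPM in AOM/DSS library 5, and at 1.14 to 10.1 CPM in the other 9 libraries. The plasma and B cell list mean was 2.88 in creatine library 3 and 2.54 in AOM/DSS library 5, and -2.80 to 1.30 elsewhere.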
